A study of Macaca mulatta with 8 samples.

How the data were processed

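Bulk ATAC-seq was done with the Omni-ATAC protocol on 8 libraries of rhesus macaque cortex cells, 2 technical libraries from 1 culture at each of 4 stages, per the labels' protocols. The submitters' processing notes name cutadapt 4.4, Bowtie2 2.5.1, SAMtools 1.15 and the genome build rheMac10. The peak caller, its threshold, any Tn5 offset and whether libraries were pooled are not given in the sources used here. The authors deposited 1 table of 112696 merged regions, without a header. For each region it gives the position and the names of the peaks merged into it, and each peak name carries a code of the set it was called in. The 4 macaque codes match the stages in the labels, and they were the only measurement used: a region counts as called at a stage when it holds at least 1 peak of that stage.

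The table also holds 8 columns of values that carry no names. They could not be matched to libraries without relying on their order or values, so they were not used in any step, and depth per library was not used here. The planned tests, edgeR on counts with age as a number and limma camera on gene lists, need these values and were not run. Comparisons of the peak sets took their place, chosen after the table was seen. Another 40338 regions hold only lifted peaks of sets that the labels do not define, and were left out, which leaves 72358 regions. Lifted peaks merged with stage peaks were not separated from them, so the bounds of such regions may rest on both. The deposited peak names had gaps in their numbering, from 12.6% of numbers at E60 to 34.8% at E50 (16.4% at E80 and 26.5% at E85). The stage peak names also carry the tag nativeFiltered. Both point to a filter before deposit, which the sources used here do not describe. The sets held 19833, 61956, 60278 and 30701 peaks at E50, E60, E80 and E85. A region not called at a stage may have been open below the threshold, and set size limits every comparison except that of E60 with E80.

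All sequence names were found in the Mmul_10 assembly report, the assembly that rheMac10 names, and no region ended beyond its sequence. Gene models were those of NCBI for that assembly, with 21122 protein-coding genes. Regions within 1000 bp of a transcription start of a protein-coding or lncRNA gene were called promoter, then exon, intron or intergenic, and all but promoters are called distal. A gene's locus was its body and the 5000 bp upstream of it, and 16328 loci held at least 1 region. Regions with at least 20 matches of 25 bases to the mitochondrial genome were called mitochondrial-like. Coordinates are 1-based.

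Contrasts counted the regions called at 1 stage and not at the other, and late-only (E80 or E85, neither of E50 and E60) against early-only regions. Shares have exact Clopper-Pearson 95% intervals, which cover counting error alone. Gene lists, 21 in number, were fixed with the motifs and the definitions of promoter and locus before the data were examined. Of the listed symbols, TUBB3, TLE4 and ZBTB20 were not found under that name in the annotation. A list's late-only share was set among 10000 random lists, each gene replaced by one of about 200 genes nearest in number of regions, and the percentile describes these sets. For 31 consensus motifs, the share of regions with the motif on either strand within 150 bp of the centre was compared with shared regions matched on GC content (bins of 5%) and on promoter or distal, by Fisher's exact test with Benjamini-Hochberg adjustment over 62 tests and a threshold of 0.05. Reversed motifs served as controls.

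The rule for named genes was written for fold changes and was adapted after the table was seen. It took the 12 loci on each side with the largest difference between late-only and early-only regions, 5 on each side per stage contrast, leading members of each list, and the widest autosomal regions called at both stages of an age group alone. Loci had at least 2 regions, the median, and a named gene symbol. A difference in counts favours loci with many regions, and no locus was tested on its own. Other list members are named where they were singled out after their values were seen. On simulated data over 16328 loci, the list method called 48 of 50 lists with a late share lowered to 0.2, 50 of 50 raised to 0.8, and 0 of 50 unchanged lists. On simulated motifs in 11313 late-only regions, it recovered 6 of 10 planted odds ratios of 1.5 and called 0 of 21 unchanged ones. Alternatives were autosomes, promoters, gene bodies or distal regions alone, regions of at most 1 kb, peaks in place of regions, each culture left out, other motif windows and backgrounds, and lists without NFIA, NFIB and NFIX. Python 3.11.15, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0, PyRanges 0.1.4 and matplotlib 3.10.9 were used.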

Results

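Chromatin accessibility was measured by ATAC-seq, in which Tn5 transposase cuts open DNA, in primary cortex cells of the rhesus macaque at 4 stages: post-conceptional days 50, 60, 80 and 85, named E50, E60, E80 and E85. The cells came from frozen cortical tissue that was dissociated and grown in a medium that favours progenitors. Each stage had 1 culture and 2 technical libraries taken from it, 8 libraries in all. The series concerns HAQERs, genome segments that changed quickly in human ancestry, in cortical development. Those segments were not analysed here, and the comparisons below describe the macaque stages. The unit of all results is the merged region, a stretch of the rheMac10 genome to which the authors assigned the peaks of 1 or more stages. A region may also hold lifted peaks of other sets, which can affect its width and centre. With 1 culture per stage, no difference between stages has a replicate check. Intervals and p-values over regions compare these peak sets, not ages, and regions are not independent replicates. Read depth per library was not used here.

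The stages shared a core of promoter-rich regions, and differed mostly in distal regions called at E60, at E80 or at both. Of 72358 regions with a peak of at least 1 stage, 17025 were called at all 4 stages and 21251 at E60 and E80 alone. A further 11835 were called at E60 alone and 9599 at E80 alone. E60 had 59928 regions and E80 had 58122, against 28982 at E85 and 18819 at E50. Regions called at all 4 stages were wide, with a median of 1005 bp, and 50.5% of them lay within 1000 bp of an annotated transcription start. That share was 10.6% for E60-alone regions and 5.38% for E80-alone regions. Of the E50 regions, 90.5% were called at all 4 stages, while 228 were called at E50 alone.

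**Figure D1:**
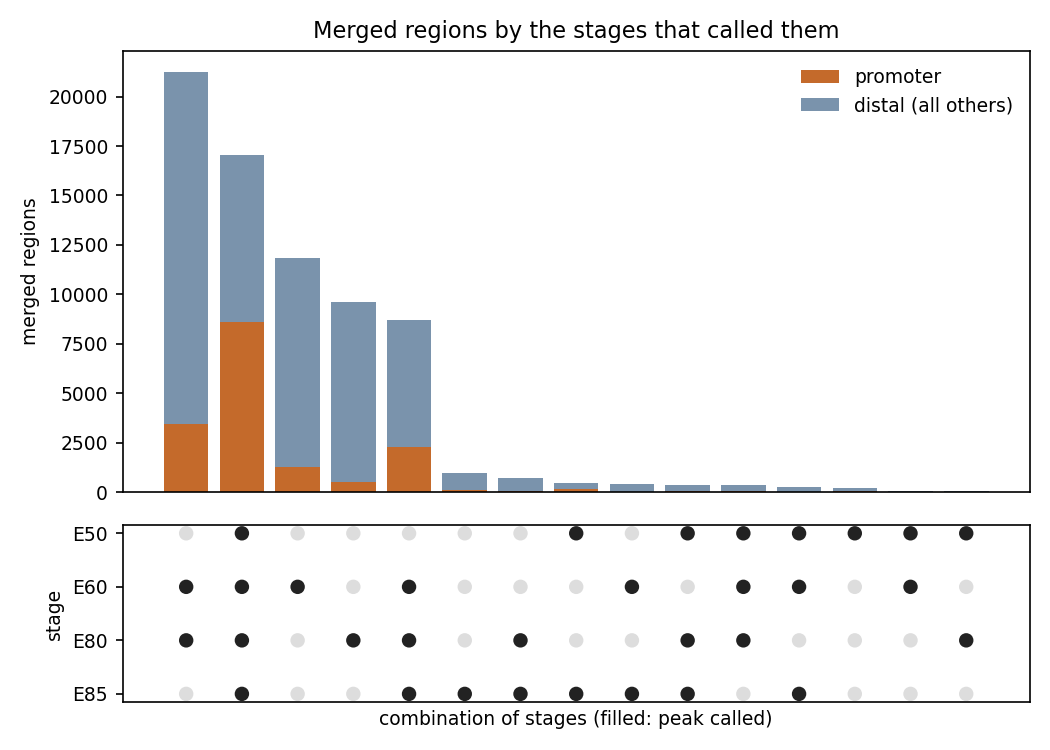
Bars give the number of merged regions for each combination of stages that called them, split into promoter and distal regions. Filled dots below mark the stages. The tallest bars are E60 with E80 (21251 regions) and all 4 stages (17025 regions).

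The comparison of E60 with E50 asked which regions were called at 1 of these stages and not at the other. Nearly all such regions were called at E60: 42226 against 1117 at E50, so 97.4% of the discordant regions were in the E60 set (exact 95% interval 97.3 to 97.6). MSI2, which encodes an RNA-binding protein of neural progenitors, had 40 regions called at E60 and not at E50, and none the other way. GSE1 had 41 against 1 and AUTS2 had 37 against 0. At E50, PTPN6, REX1BD, SELENOW, SF3A1 and ZNF596 each had 2 regions that E60 lacked, and none the other way. Promoters made up 26.8% of the E50-specific regions and 16.8% of the E60-specific ones. Among the 21 gene lists, only the cell-cycle list had a percentile outside the central 95% of random lists. It held 3 regions called at E60 alone of the pair and 1 at E50 alone, and its share, 75.0%, equalled the lower limit of the range. About 1.05 lists or fewer would lie outside by chance. The upper limit of each random range was 100%, which no share can exceed. The E50 set held 19833 peaks and the E60 set 61956, and the direction of this contrast cannot be separated from the sizes of the sets.

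E60 and E80, 20 days apart, had sets of nearly equal size and shared 47343 regions. E60 had 12585 regions that E80 lacked, and E80 had 10779 that E60 lacked, so 46.1% of the discordant regions were in the E80 set (exact 95% interval 45.5 to 46.8). In 5 of 19 lists the E80 share lay below the central 95% of random lists, against about 0.95 or fewer by chance. These lists were radial glia, deep-layer neurons, astrocytes, late progenitor timing and rostral area. They are not independent: astrocytes and late progenitor timing share NFIA, NFIB and NFIX, and radial glia and rostral area share PAX6. The count without these genes was not taken for this pair. At more loci E60 had the larger number of stage-specific regions (3302 against 2817). CAMTA1, a calmodulin-binding transcription activator gene, had 17 regions called at E80 and not E60, against 3. AOPEP had 11 against 0, and KCNMA1, which encodes a calcium-activated potassium channel, had 15 against 4. In the other direction MSI2 had 18 E60-specific regions against 4, CELF4 had 13 against 0, and RBFOX1, a neuronal splicing factor gene, had 12 against 0. BCOR, on the X chromosome, had 12 against 0. Of the regions on autosomes and the X chromosome, the X held 3.52% of the E60-specific and 1.83% of the E80-specific ones. Whether BCOR departs from this chromosome-wide difference was not tested. E80-specific regions were narrower (median 281 bp against 350 bp) and less often promoters (5.87% against 10.5%).

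E80 and E85, 5 days apart, shared 26878 regions. E80 had 31244 regions that E85 lacked, and E85 had 2104 that E80 lacked, so 6.31% of the discordant regions were in the E85 set (exact 95% interval 6.05 to 6.58). KCNMA1 had 30 regions called at E80 and not E85 and none the other way, AUTS2 had 30 against 1, and OPCML, a neuronal cell adhesion gene, had 27 against 1. SH3RF3 had 25 against 0 and DLG2, which encodes a postsynaptic scaffold, had 26 against 1. DOK5 had 4 regions called at E85 and not E80, against 1. ACSM5, ARHGEF38, ETFA and IL6R each had 2 against 0. None of the 21 gene lists lay outside the central 95% of random lists. The lower limit of each random range was 0%, which no share can fall below. The E85 set held 30701 peaks and the E80 set 60278, and this contrast too follows the sizes of the sets.

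Late-only regions, called at E80 or E85 and at neither earlier stage, numbered 11313. Early-only regions, called at E50 or E60 and at neither later stage, numbered 12132. The late share was 48.3% (exact 95% interval 47.6 to 48.9). More loci had an excess of early-only regions (3201) than of late-only regions (2907). Of the late-only regions 84.8% were called at E80 alone, and of the early-only regions 97.6% at E60 alone. The comparison is therefore close to E80 against E60, and without the E60 culture 99.3% of the discordant regions were late-only, without the E80 culture 4.83%, and without the E50 culture 50.6%. Among promoters the late share was 33.4%.

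Loci were ranked by difference in counts, which favours loci with many regions: CAMTA1 held 48 and MSI2 65, against a median of 2. Among the loci with the largest excess of late-only regions, CAMTA1 had 18 late-only regions and 3 early-only ones. DLGAP2, a postsynaptic scaffold gene, had 12 against 2, KCNMA1 14 against 4 and DLG2 13 against 5. ASIC2, an acid-sensing ion channel gene, had 8 against 1. PTPRE, a receptor-type phosphatase gene, had 9 against 0, GALNT17 had 8 against 0, and PLEKHA7 and TMTC2 each had 7 against 0. AOPEP had 11 against 1, DPF3 had 9 against 1, and PAPPA, which encodes a protease that cleaves IGF-binding proteins, had 8 against 1. CAMTA1 lies on chromosome 1 from 216747437 to 217726690, and KCNMA1 on chromosome 9 from 60112455 to 60947862.

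Among the loci with the largest excess of early-only regions, MSI2 had 18 early-only regions and 4 late-only ones. CELF4 had 13 against 0, and RBFOX1 and BCOR each had 12 against 0. NFIA and NFIX, genes of nuclear factor I transcription factors, had 11 and 9 against 0. CTNND2, which encodes a catenin of the synapse, had 12 against 1, and SDK2 had 10 against 1. ADGRL2, FAM49A and RALGAPA2 each had 9 against 0. MAP2, a neuronal microtubule protein gene, had 8 against 0. NFIA lies on chromosome 1 from 162988663 to 163372064, and had 8 regions at E50, 27 at E60, 17 at E80 and 10 at E85. MSI2 lies on chromosome 16 from 39118886 to 39552607, and had 21, 61, 47 and 24 regions at these stages.

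**Figure D2:**
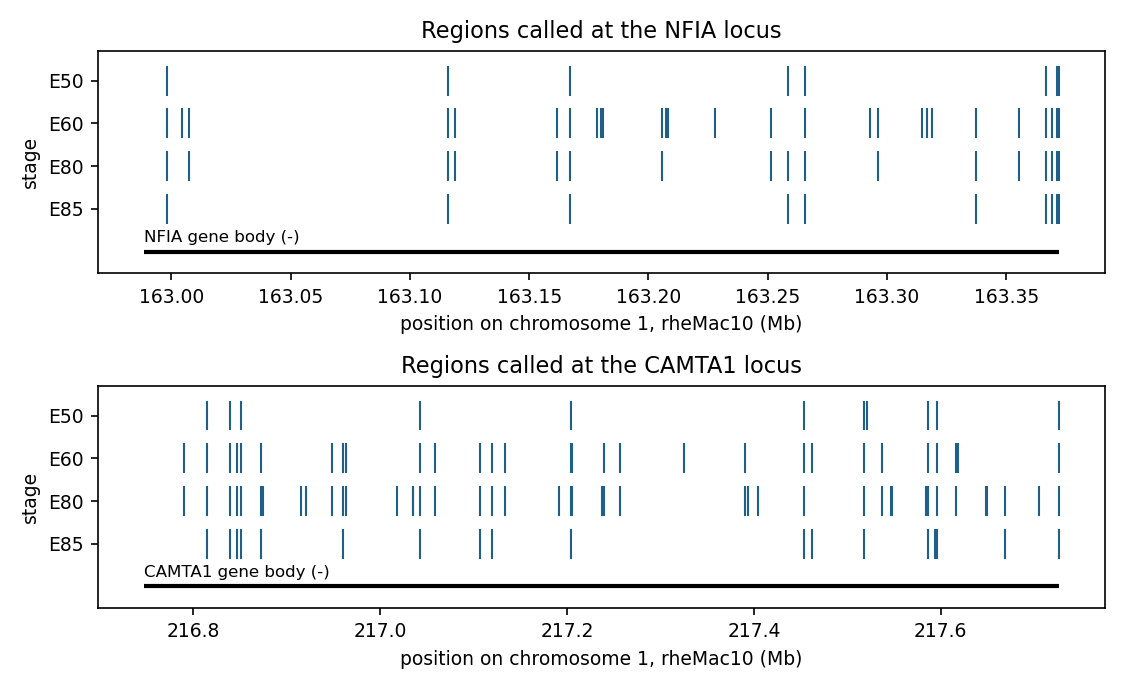
Each vertical line marks a region called at a stage (rows) along NFIA and CAMTA1 (horizontal axes, Mb on chromosome 1 of rheMac10), with the gene body as a black bar. NFIA had 27 regions at E60 and 17 at E80, and CAMTA1 had 29 at E60 and 43 at E80.

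Fixed lists of cell type and pathway genes were compared with random lists matched on the number of regions per locus. In 5 of the 20 lists that held any discordant region, the late-only share lay below the central 95% of random lists, and in none above. About 1 or fewer would lie outside by chance, since some lists held too few regions to lie outside at all. The 5 lists are not independent, as some share genes. Without the E80 culture, or with promoters alone, no list lay outside. These settings could hardly place the 5 lists below the range. Without E80 they held no late-only region, the lowest share possible. With promoters alone they held 1 to 6 early-only or late-only regions. Without the E60 culture the astrocyte list alone of the 5 stayed outside, with 2 early-only and 51 late-only regions. Those 2 were not at NFIA, NFIB or NFIX, as the late progenitor timing list holds these genes and had none. The cell-cycle list came to lie outside without this culture, with 1 early-only and 3 late-only regions. The rostral area list had 16 early-only regions and no late-only one (percentile 0.01 among 10000 random lists). In it 7 members had more early-only regions and 2 had equal numbers. MEIS2 had 7 early-only regions, and PAX6, a radial glia and patterning factor, had 2. The deep-layer neuron list had 17 against 3 (percentile 1.21), with 6 members to the early side and 2 equal. In distal regions alone it lay within the range, at percentile 3.90. FOXP2 had 5 against 0 and SOX5 5 against 2. FEZF2, which specifies subcerebral projection neurons, had 3 against 0 and was called at its promoter at E50 and E60 alone. The interneuron and ventral forebrain list had 21 against 6 (percentile 2.23), with 8 members to the early side, 4 to the late side and 4 equal. It lay within the range on autosomes alone (percentile 3.80), without the E85 culture (3.95) and in the E60 and E80 pair (2.63). GAD1, which makes the transmitter GABA, had 5 against 0, and GAD2 and DLX1 each had 3 against 0.

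The astrocyte list had 30 early-only and 4 late-only regions (percentile 0.02), and the late progenitor timing list also had 30 and 4 (percentile 0.02). Both hold NFIA, NFIB and NFIX, with 11, 7 and 9 early-only regions and no late-only one. Without these 3 genes each list had 3 early-only and 4 late-only regions, at percentiles 71.9 and 69.8, so the position of both lists rested on them. Of the 16 astrocyte genes, 5 had more early-only regions, 4 had more late-only regions and 7 had equal numbers. CD44, ALDH1L1, GJA1 and SPARCL1 each had 1 late-only region and no early-only one, while GFAP had 2 early-only regions.

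**Figure D3:**
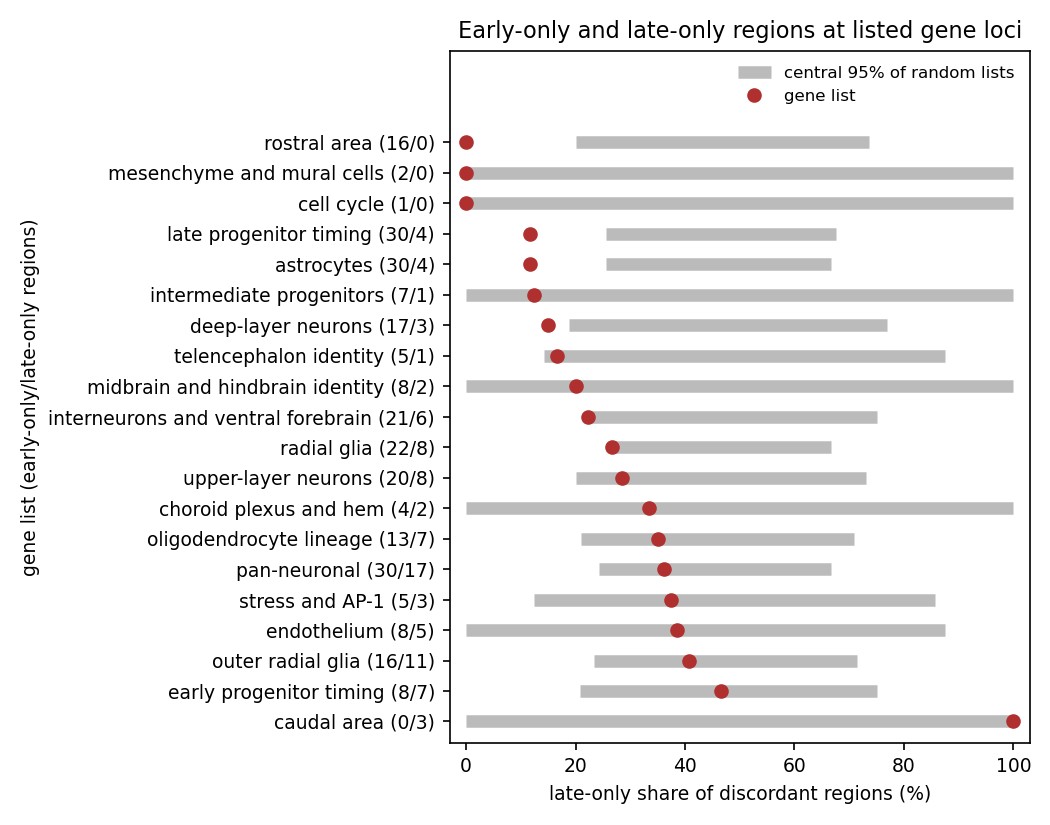
Points give the late-only share of the early-only and late-only regions at the loci of each list, with both numbers after its name. Grey bars span the central 95% of 10000 random lists. The rostral area list (16 early-only, 0 late-only) and the 2 lists with nuclear factor I genes (30 and 4 each) lie to the left of their bars.

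The other lists lay within the range of random lists, but some held too few regions to leave it. The caudal area list had late-only regions alone, the highest share possible, yet lay at percentile 95.1. The mesenchyme and mural cell list and the cell-cycle list had early-only regions alone, and lay at percentiles 5.10 and 9.79. The radial glia list had 22 early-only and 8 late-only regions (percentile 2.67), with GLI3 at 9 against 1. In the E60 and E80 pair its share lay just outside, at percentile 1.56. The outer radial glia list had 16 against 11, with PTPRZ1 at 7 against 0 and ITGB5 at 2 against 5. Intermediate progenitor genes had 7 against 1. All 9 had a promoter called at E60 and 8 at E80, against 2 at E50 and 3 at E85. Among all protein-coding genes the share with a promoter call was also higher at E60 (64.7%) and E80 (63.2%) than at E50 (44.3%) and E85 (53.0%). Pan-neuronal genes had 30 against 17. MAP2 had 8 against 0, and GAP43, a growth cone protein gene, had 0 against 5. The upper-layer neuron list had 20 against 8, with CUX2 at 5 against 0 and UNC5D at 2 against 5. The oligodendrocyte lineage list had 13 against 7, early progenitor timing 8 against 7, telencephalon identity 5 against 1, midbrain and hindbrain identity 8 against 2, and the caudal area list 0 against 3. The stress and AP-1 list had 5 against 3, and the cell-cycle list 1 against 0.

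None of the 12 microglia genes had a promoter call at any stage, and their loci held no early-only or late-only region. The endothelium list had 8 early-only and 5 late-only regions, the mesenchyme and mural cell list 2 and 0, and the choroid plexus and hem list 4 and 2. At E60, promoters were called for 5 of the 10 endothelium genes and 8 of the 13 mesenchyme and mural cell genes, against 64.7% of all protein-coding genes. PDGFRB, a pericyte receptor gene, had promoter calls at all 4 stages. FLT1, an endothelial receptor gene, had 5 early-only and 2 late-only regions and a promoter call at E60 alone.

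Early-only and late-only regions differed in transcription factor motifs. The AP-1 motif TGASTCA, bound by FOS and JUN dimers, was within 150 bp of the centre of 10.8% of early-only regions and 24.7% of matched shared regions (odds ratio 0.367, 95% interval 0.342 to 0.394, adjusted p = 3.92e-180, Fisher's exact test with Benjamini-Hochberg adjustment over 62 tests). It was in 38.1% of late-only regions and 27.8% of their matched shared regions (odds ratio 1.60, interval 1.51 to 1.69). The reversed AP-1 control moved the same way. Its odds ratio was 0.778 in early-only regions (interval 0.695 to 0.870). In late-only regions it was 1.47 (interval 1.33 to 1.63), close to that of the motif. The TEAD motif ACATTCC was in 4.02% of early-only and 9.84% of late-only regions. The homeobox motif TAATTA was in 14.7% of early-only regions and 7.12% of late-only regions. The E-box CAGCTG of proneural factors was in 31.4% and 21.1%. In early-only regions 12 of 31 motifs were more frequent than in shared regions and 9 less frequent. In late-only regions 3 were more frequent (AP-1, TEAD and STAT) and 13 less frequent. Reversed controls passed the same threshold for 4 motifs in early-only and 5 in late-only regions. In early-only regions MEIS (odds ratio 1.23, control 1.16) and KLF/SP (0.822, control 0.835) differed little from their controls.

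Set directly against each other, with matched GC content and feature, late-only regions had AP-1 more often than early-only regions (37.6% against 11.6%, odds ratio 4.58, 95% interval 4.26 to 4.92), and also TEAD (odds ratio 2.39) and STAT (1.56). They had less often the homeobox motif (odds ratio 0.377), POU (0.426), CAGCTG (0.593), RFX (0.616) and SOX (0.645). The reversed sequences, which served as controls, differed past the threshold for 8 of 31 motifs, among them AP-1 (odds ratio 1.78), the homeobox motif (0.575) and SOX (0.862). For these 3 motifs the controls moved in the same direction as the motif, while for TCF/LEF the motif (0.875) and its control (1.26) moved apart. The reversed homeobox sequence, ATTAAT, still holds the TAAT and ATTA of the motif, so it was not a neutral check. The motifs MEIS (0.774, control 0.756), KLF/SP (0.671, control 0.693) and NR2F (1.63, control 1.46) had controls about as large as themselves. For MEIS and KLF/SP the reversed sequence keeps most of the motif, so a similar odds ratio could not show a lack of specificity. Controls of POU, CAGCTG and RFX did not pass, but were in 0.136%, 0.505% and 0.233% of early-only regions. Their intervals held the motif's own odds ratio, so they could not serve as a check. The AP-1 difference followed E80 and not both later stages. Among distal regions, AP-1 was in 43.7% of those called at E80 alone (exact 95% interval 42.7 to 44.7), 16.5% of those called at E80 and E85 alone (13.9 to 19.5), and 7.71% of those called at E85 alone (6.01 to 9.71). In E60-alone regions it was in 11.6%, in those called at E60 and E80 alone in 32.7%, and in those called at all 4 stages in 19.6%.

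**Figure D4:**
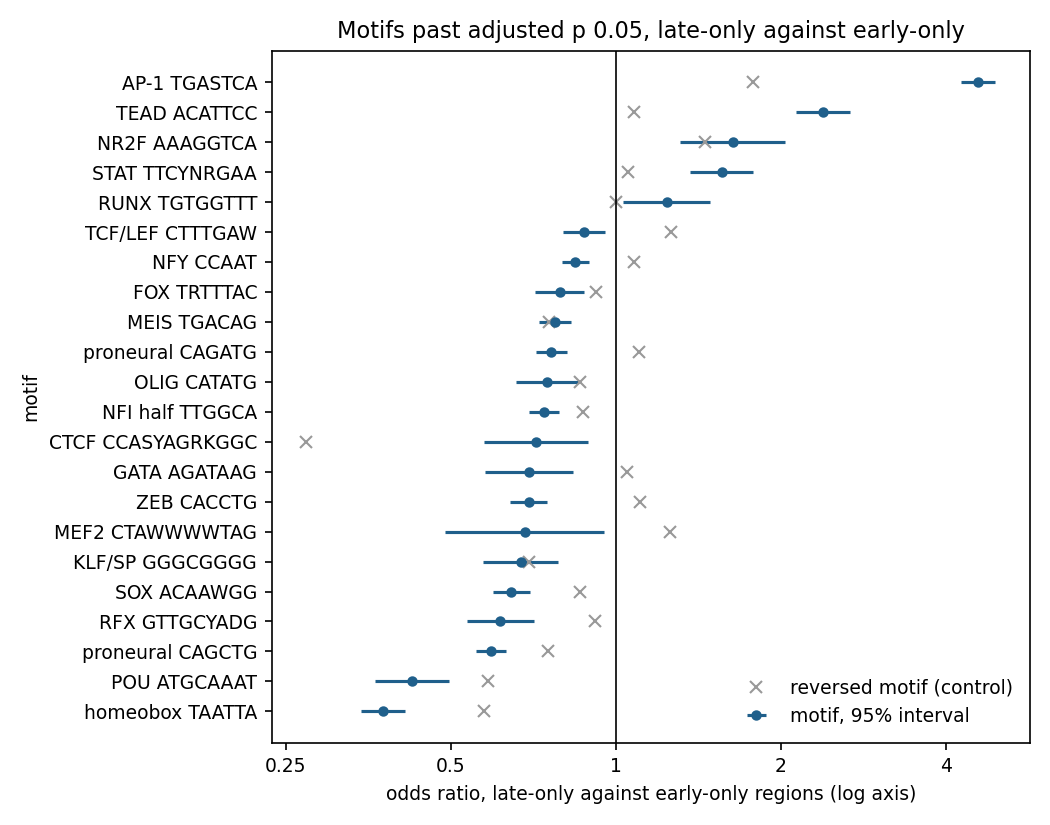
Points give the odds ratio of each motif in late-only against early-only regions (log axis) with 95% intervals, for motifs with adjusted p under 0.05. Crosses give the reversed motif. AP-1 (4.58) and TEAD (2.39) lie farthest to the right, and the homeobox motif (0.377) and POU (0.426) farthest to the left.

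Few regions were called at both stages of one age group and at neither of the other: 747 at E80 and E85 alone, and 69 at E50 and E60 alone. The widest early one lay in GFAP, the gene of the astrocyte intermediate filament, on chromosome 16 from 56173746 to 56177312. It overlapped an exon and was 3567 bp wide. The next, on chromosome 2 from 118537877 to 118539754, overlapped the FEZF2 promoter. The widest late one lay in an intron, nearest to the start of TPPP, a tubulin-binding protein gene, on chromosome 6 from 622974 to 625159. The next was intergenic, 50379 bp from the nearest start, that of NR1D2, a clock-related nuclear receptor gene, on chromosome 2 from 23662502 to 23664281.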

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

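The tests of list size, of the X chromosome, of distal, CpG-poor and placed regions, of loci outside the neural lineage, and of width, GC content and feature over all neural lists were chosen after the result was seen, and so was the comparison without the nuclear factor I genes.

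The table held 40338 regions made of lifted peaks alone, of sets that the labels do not define. They stood out as signal outside the stage comparisons, and no control shows what level to compare them with.

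The E60 set held 2 Y chromosome regions, against 6 at E50, 30 at E80 and 11 at E85. Promoters of ZFY, DDX3Y, UTY and EIF1AY were called at E50, E80 and E85 and not at E60. The size of the peak list argues the other way, since the larger E60 set held fewer Y regions per autosomal region than E50 and E85 together (odds ratio 0.114, interval 0.0303 to 0.430, Fisher's exact p = 7.33e-05). The X chromosome was enriched in regions called at E60 and not E80 (odds ratio 1.95, interval 1.65 to 2.32), which is consistent with a female E60 animal and male animals at the other stages. As a hypothesis, the sex of the animals may thus differ together with stage, and the labels give no sex to check it.

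E50 and E85, the stages farthest apart in age, called 456 regions that neither E60 nor E80 called, against 69 for E50 with E60 alone and 47 for E50 with E80 alone. The tests set E50 with E85 alone against the sum of E50 with E60 alone and E50 with E80 alone. Promoters were not the whole source, since distal autosomal regions alone gave 265 against 98 (exact binomial p = 6.98e-19). Nor were CpG-rich regions, since those with a CpG observed to expected ratio under 0.6 gave 247 against 95 (exact binomial p = 9.90e-17). Unplaced sequence was not either, since placed chromosomes gave 416 against 114 (exact binomial p = 2.26e-41). These p-values take an even split of each pair of counts, which sets of unequal size and overlap need not give. A processing step or batch that E50 and E85 shared stays open, as the sources used here name none, and so do peak thresholds and animals. No biological explanation was tested.

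Loci of all 11 progenitor, neuronal and glial lists, taken whatever their own share, held 185 early-only and 74 late-only regions. Width, GC content and feature of the regions were not the whole cause: against all other regions the odds ratio was 0.425 before and 0.468 after stratifying by them (interval 0.353 to 0.620). Without NFIA, NFIB and NFIX it was 0.550 (interval 0.412 to 0.734). Whether any developmental locus would show it cannot be told apart, because endothelial, mesenchymal and microglial loci held too few regions, 5 late-only and 10 early-only (odds ratio 1.30, interval 0.449 to 3.79, Fisher's exact p = 0.770). Age, animal, sex and the cell makeup of each culture are confounded with stage and stay open.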

How the results depend on the processing

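The alternatives without mitochondrial-like regions, with distal regions alone, with promoters alone in shares of regions, with regions of at most 1 kb, with peaks in place of regions, with direct or width-matched motif backgrounds, with lists on autosomes and with lists lacking nuclear factor I genes were chosen after the data were seen. Promoters alone were planned for loci and lists. No paired analysis was possible because the 8 value columns carry no names or replicate numbers. For the same reason alternatives on normalization, DESeq2, low-count filters, the replicate block, single replicates, GC offsets, fold minimum, estimated correlation and the 1000 smallest p-values were not run. The late share of discordant regions (48.3%) ran from 4.83% to 99.3% with each culture left out. Without E50 it turned to 50.6%, without E60 to 99.3%, without E80 it was 4.83% and without E85 43.8%. It was 49.7% in distal regions, 33.4% in promoters and 49.6% in peaks. The share of loci with more late-only regions (47.6%) ran from 2.96% (without E80) to 99.2% (without E60), with 51.6% without E50, 41.9% without E85, and 31.4% with promoters alone. For E60 against E50 the share of discordant regions in the later set was 97.7% in regions of at most 1 kb, 97.7% in distal regions and 95.9% in promoters. For E80 against E60 it was 47.4% in distal regions and 32.3% in promoters, and for E85 against E80 7.36% in promoters. The number of lists outside the random range, 5, was 0 with promoters alone, 3 without NFIA, NFIB and NFIX, and 0 (without E80) to 6 (without E50) with a culture left out, with 2 without E60. Against the median of random lists, promoters alone turned the interneuron list to 16.7 points above and the astrocyte list to 8.33 above, from 4 and 3 regions. Without the nuclear factor I genes the astrocyte and late timing lists turned to 9.77 and 10.1 points above. Motif pairs past the threshold, 37, stayed within 33 to 40 against shared regions. Late-only against early-only regions gave 42, which counts 1 comparison from both sides and is not the same measure. In early-only regions, odds ratios turned above 1 against late-only regions for CTCF (1.50, and 1.70 with width), NRF1 (1.04), ETS (1.10 and 1.11), KLF/SP (1.43 and 1.31) and EGR (1.38 and 1.20), and with shared regions matched on width for KLF/SP (1.00) and EGR (1.07). Late-only regions had these motifs less often than shared regions, which by construction raises the direct ratios. The cause of the other changes was not tested. Among the remaining comparisons of single motifs, direct ones are counted from both sides. Of all these remaining comparisons, 156 kept their direction and side of the threshold and 18 lost the threshold. Of those of single lists, 26 stayed outside the random range and 15 came inside it. Each list called outside stayed so in 4 to 6 of 9 alternatives, but not all of these could decide. Leaving out NFIA, NFIB and NFIX left the deep-layer neuron, interneuron and rostral area lists as they were. Without E80 the rostral area list had 37 early-only and 0 late-only regions, the lowest share possible, yet lay at percentile 12.3. With promoters alone these 5 lists held 1 to 6 such regions.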

Other observations

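The nuclear factor I motif test was written down before motifs were counted, while the test of that motif at E85 alone, the mitochondrial-like regions and the motif shares by combination of stages were chosen after the results were seen.

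Distal regions called at E60 alone held the homeobox motif in 15.9% (exact 95% interval 15.2 to 16.6) and CAGCTG in 32.3% (31.4 to 33.2). Those called at E80 alone held them in 7.15% (6.62 to 7.69) and 20.8% (20.0 to 21.7). TEAD sites were in 10.2% of E80-alone regions (9.57 to 10.8), 12.7% of regions called at E80 and E85 alone (10.3 to 15.4), and 4.18% of E60-alone regions (3.81 to 4.58). In E85-alone regions they were in 6.78% (5.18 to 8.67).

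As a hypothesis, the excess of early-only regions at NFIA, NFIB and NFIX may go with more nuclear factor I sites in early-only regions. The short site TTGGCA was less frequent in late-only than in early-only regions (odds ratio 0.740, interval 0.694 to 0.788, adjusted p = 7.07e-20, Fisher's exact test), as the hypothesis predicted. Its reversed control did not pass the threshold (odds ratio 0.870, interval 0.733 to 1.03, adjusted p = 0.296, Fisher's exact test). That control was in 2.41% of late-only and 2.76% of early-only regions, against 21.7% and 27.3% for the site. Its interval holds the site's own odds ratio, so the control cannot show that the difference is specific to the site. Among distal regions the site was in 20.6% of E80-alone, 26.8% of E60-alone and 27.4% of E80 and E85 alone regions (interval 24.1 to 30.8 for the last). It was in 33.4% of E85-alone regions (interval 30.3 to 36.7), above the E60-alone share and against the prediction made for E85. That prediction took E85-alone regions to lack the nuclear factor I loci. With 967 E85-alone regions few could lie at these loci, so the share cannot decide the hypothesis for E85. The test of late-only against early-only regions is not specific, since 17 of 31 motifs were less frequent in late-only regions.

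Nuclear sequence resembling the mitochondrial genome made up 69 regions, 26 of them called at all 4 stages. At E80 alone 16 were called, against 0 at E60 alone, and the cause of this difference was not tested. The widest match lay on chromosome 3 from 16062526 to 16070152 and was called at all 4 stages.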
